A study of Rattus norvegicus with 6 samples.

How the data were processed

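RNA from 6 samples of dorsal wound tissue of diabetic rats was extracted with TRIzol, made into messenger RNA libraries and sequenced in pairs of reads on a DNBSEQ-T7 instrument, per the labels' protocols. The groups, control and DST-MNs with 3 libraries each, were taken from the sample titles, and each column of the table was matched to its library by the library name. The labels call the samples biological replicates.

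The authors deposited 1 table with 4 kinds of value per library for 18825 genes, each gene with its Entrez identifier and symbol. The estimated counts deposited by the authors are read counts per gene with no scaling, per the file headers, of which 90.6% to 91.4% are whole and the rest have up to 2 decimals. The FPKM values, per the file headers, are fragments scaled by gene length and library, and were not tested. The TPM values, per the file headers, sum to 1000000 in a library, within rounding, and were used for an added alternative. The normalised counts are a signal the authors made by dividing the counts of a library by 1 factor, as the near constant ratio within each library shows, and were not tested. Reads were handled against the build mRatBN7.2, per the submitters' processing notes, and the aligner, the counter and their versions are not given in the sources used here. All per-sample columns were matched, and 211 genes had 0 counts in every library. The reference table used for names was of another assembly, GRCr8, so no coordinates are given, and 18588 of the identifiers were in it, 18298 of them protein coding. How the counting divided reads between similar genes is not given, so genes with close copies are uncertain.

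Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 at its minimum count of 10, which left 14427, and were scaled with TMM factors and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 30.2%. CPM are counts scaled to a common library total with TMM factors, and log2 CPM used a prior count of 2. The standard error of a log2 change is its size divided by the square root of the F statistic. A gene at 0 in a group is given as a bound against 3 counts over that group, and a gene with 1 to 3 counts as a ratio of scaled counts with its exact 95% counting interval. These counting intervals and floors pool the counts of a group and cover counting error only, not spread between libraries. The 95% intervals of log2 changes were made from the standard error and do include that spread. The labels name no molecular identifiers. Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over 37 lists with at least 5 measured genes, and again with an estimated correlation and with fry. Of 729 list entries, 712 were matched by symbol, 9 through the reference and 8 not at all. Genes counted as measured are those that also passed the count filter, so list medians and shares leave out listed members with too few counts. For tissue nearly absent from the controls, these members passed mainly through the treated libraries.

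The groups, the test, the 37 lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 highest and 10 lowest log2 changes among genes past the threshold with a symbol that is no LOC, RGD or Ensembl identifier, a mean log2 CPM of at least 1 and groups that do not overlap. It also took up to 4 members with the smallest p from each list past the camera threshold or with a gene past the threshold. Always named were Tgfb3, Tgfb1, Col1a1, Col3a1, Vegfa, Pecam1, Il1b, Tnf, Il6, Il10, Arg1, Nos2, Mrc1, Krt14, Acta2, Odc1 and Sat1. Krt71 counts by library were given after they were seen. Some genes that the rule or a list would name are not reported here.

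The alternatives were DESeq2 1.42.0 size factors, upper-quartile factors and total counts in place of TMM, no count filter, at least 10 counts in every library, the Wald test of DESeq2, limma-voom, the replicate number as a block, glmTreat against a 1.5-fold change, and each library left out in turn. A limma trend test on log2(TPM + 1) of genes with a mean TPM of at least 1 was added after seeing the data. Library totals of 12545206 to 13818548 counts set the depth. Counts were simulated for the 14427 genes with these means and library sizes, and 14272 genes passed the filter. On them the test of DST-MNs against control recovered 15 of 100 genes changed 2-fold and 75 of 100 changed 4-fold, with 5 false calls. The median fitted log2 changes were 0.98 and 2.01. Each gene was drawn independently, while genes of a tissue vary together in the real libraries, so recovery and false calls may differ there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.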

Results

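Messenger RNA was sequenced from dorsal skin wounds of male diabetic rats, in which a diet high in fat and sucrose was followed by streptozotocin, a toxin of the insulin-producing beta cells. The wounds went through the full thickness of the skin. The 6 libraries formed 2 groups of 3, untreated wounds (control) and wounds treated with DST-MNs. These are microneedles carrying dental pulp stem cell spheroids regulated with spermidine, a polyamine, and with the growth factor TGF-β3. The labels call the 3 libraries of each group biological replicates and give no day of collection. Estimated read counts were listed for 18825 genes. Totals ran from 12545206 counts in DST-MNs replicate 3 to 13818548 in control replicate 3. The collagen transcripts Col1a1 and Col3a1 took 2.79% to 3.85% and 2.16% to 4.14% of the counts of a library. Pairs of libraries within a group differed by 32.7 to 72.3 times the counting noise (chi-square per degree of freedom), and pairs between the groups by 35.9 to 98.2 times. Control 1 was closer to DST-MNs 2 (35.9) than to control 2 (51.9) or control 3 (72.3).

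The comparison asked which genes differ between treated and untreated diabetic wounds. Cyp2b12, Elovl4 and Awat1, genes of the sebaceous gland and of lipid synthesis, rose in the treated wounds from levels close to 0 in the controls, and 4 of the 13 measured members of the sebaceous list rose. The smaller set of genes that fell held Lcn2, Timp1 and Cd163. Of 14427 genes tested, 112 changed, 95 of them higher and 17 lower after treatment (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Among them 107 changed at least 2-fold. At an unadjusted p below 0.05 there were 1414 higher and 992 lower genes. The groups did not overlap for any of the 112 genes, nor for 3305 (22.9%) of all genes tested, where chance gives 10% on average over splits of the libraries. Genes vary together, so a share above 10% is not by itself evidence of a group difference. The count of changed genes was 402, 34 and 53 without control replicates 1, 2 and 3. It was 23, 34 and 14 without DST-MNs replicates 1, 2 and 3. DESeq2 called 1070 genes, 678 higher and 392 lower, including all of the 112.

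The leading 10 genes among those that rose included enzymes of lipid metabolism. Cyp2b12 (gene ID 29295), a cytochrome P450 of sebaceous cells, rose from 0.258 ± 0.224 to 142 ± 41.4 normalised CPM (mean ± SD, n = 3). Its log2 change was 9.05 (SE 0.56, adjusted p = 0.0038, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Awat1 (679520), an acyltransferase that makes wax esters, rose by a log2 change of 6.92 (SE 0.62, adjusted p = 0.00982), from 0.207 ± 0.196 to 26.2 ± 5.48 CPM. Pnpla5 (300108), a lipase of the patatin family, and Acsm1 (361638), an acyl-CoA synthetase, rose by 7.34 (SE 0.82) and 6.75 (SE 0.64) on the log2 scale. Akr1c2 (291283), an aldo-keto reductase, rose by 6.96 (SE 0.91). The 4 control counts of Akr1c2 were all in control replicate 3, and so were the 4 of Pnpla5. Without that library the log2 bound over 3 counts was 6.94 for Akr1c2 and 7.29 for Pnpla5. Trim67 (307938) had no count in any control and 87, 98 and 106 counts in the treated libraries. It was at least 91.8-fold higher over a floor of 3 counts for the control group (adjusted p = 0.0136). Genes with 1 to 3 counts in the control group as a whole were Rnase12 (364302), Bbox1 (64564), Muc15 (690914) and Adgrf4 (501106). Bbox1 encodes the last enzyme of carnitine synthesis, and its ratio of scaled counts was 383 with a 95% counting interval of 68.4 to 15170. The ratios were 613 (110 to 24250) for Rnase12, 151 (41.4 to 1251) for the mucin Muc15 and 119 (40.4 to 579) for Adgrf4, where intervals cover counting error only. Of these 10 genes, Cyp2b12 kept its call with each library left out in turn. The others kept theirs in 1 to 5 of the 6 cases, and their highest adjusted p ran up to 0.103, for Akr1c2.

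The sebaceous gland list was higher after treatment, with a median log2 change of 3.24 over 13 measured genes (camera adjusted p = 1.89e-08; adjusted p = 0.343 with an estimated correlation). Over all genes, 4 members rose and 0 fell, and 10 rose adjusted over the list alone. Elovl4 (315851), which elongates very long chain fatty acids, rose from 1.35 ± 0.811 to 133 ± 6.87 CPM, a log2 change of 6.61 (SE 0.38, adjusted p = 0.0038, edgeR's quasi-likelihood test, Benjamini-Hochberg). It kept its call with each library left out. Awat2 (302425), a second wax synthase, rose by 6.25 (SE 0.70, adjusted p = 0.0198). It kept its call in 2 of the 6 cases with 1 library left out, with adjusted p up to 0.0899. Fasn (50671), fatty acid synthase, rose from 72.1 ± 18.9 to 213 ± 37.0 CPM (log2 change 1.56, SE 0.24). Its adjusted p was 0.0499, and 0.0524 with the size factors of DESeq2. It lost its call without any 1 library other than control replicate 1, with adjusted p up to 0.162. The median deviation of the list from the mean of the 6 libraries was -0.77, -2.79 and -1.14 in controls 1, 2 and 3 and 1.90, 1.27 and 1.93 in DST-MNs 1, 2 and 3.

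**Figure D1:**
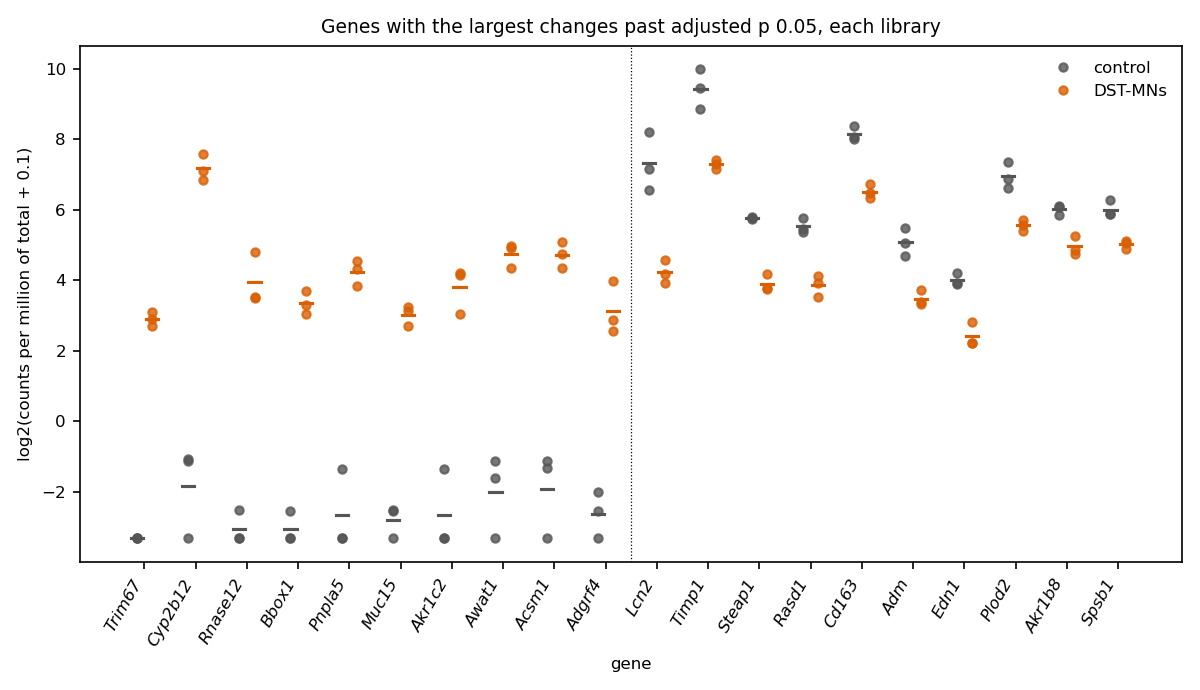
The 10 highest and 10 lowest named genes past adjusted p 0.05 are plotted for each library on the vertical axis as log2(CPM + 0.1), with CPM taken from the library total, and with control libraries in grey and DST-MNs libraries in orange. Dots are libraries and short bars are group means (n = 3), and no gene shows overlapping groups.

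Keratinocyte genes were higher in the treated wounds as lists, while no single member passed edgeR's quasi-likelihood test over all genes. DESeq2 called 10 of 14 differentiated and 2 of 12 basal genes, the replicate block 1 and 4 and voom 0 and 0, and 12 and 9 had an unadjusted p below 0.05. Of 24 listed genes of differentiated keratinocytes and the cornified envelope, the 14 measured had a median log2 change of 4.19 (camera adjusted p = 1.3e-06; adjusted p = 0.412 with an estimated correlation). Of these, 12 were higher adjusted over the list alone. Spink5, a protease inhibitor of the outer epidermis, stood at 0.622 CPM in controls and 23.1 CPM after treatment (log2 change 5.19, SE 0.99, adjusted p = 0.0885, edgeR's quasi-likelihood test, Benjamini-Hochberg). Dsg1, a desmosomal cadherin, stood at 3.90 ± 2.18 and 73.9 ± 84.1 CPM (log2 change 4.24, adjusted p = 0.131; 2.70 without DST-MNs replicate 1). The 12 genes of basal keratinocytes had a median of 2.20 (camera adjusted p = 2.67e-05; adjusted p = 0.448 with an estimated correlation). Here 9 were higher adjusted over the list alone. Their laminin gene Lama3 had a log2 change of 1.89 (SE 0.41) and the keratin Krt14 one of 3.66 (SE 1.23, adjusted p = 0.219). Krt14 stood at 61.0 ± 48.2 CPM in controls and 772 ± 727 after treatment. The treated libraries were far apart. Median deviations of the differentiated list were 3.58, -0.05 and 1.63 in DST-MNs 1, 2 and 3 against -1.25, -2.61 and -0.82 in controls 1, 2 and 3. Wound-edge and hyperproliferative keratinocyte genes had a median of 0.12 and a mean of 1.15 over 12 genes, while the test pointed down (camera adjusted p = 0.915). Their median was 1.01 without control replicate 2, 1.09 without DST-MNs replicate 2, 0.31 without DST-MNs replicate 3 and -0.20 without DST-MNs replicate 1. None of them passed over all genes or adjusted over the list alone, while 5 had an unadjusted p below 0.05 and DESeq2 called 1 higher and 1 lower.

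Hair follicle genes had a median log2 change of 3.52 over 11 measured of 28 listed genes (camera adjusted p = 0.0218; adjusted p = 0.642 with an estimated correlation). None passed over all genes and 1, the BMP and WNT antagonist Sostdc1 (log2 change 4.18, SE 0.93), was higher adjusted over the list alone. At an unadjusted p below 0.05 there were 3, and DESeq2 called 2. The list rested on DST-MNs replicate 1, whose median deviation was 4.42 against -1.13 and -1.05 in the other treated libraries. Without it the median was -0.16 (camera adjusted p = 0.916). The inner root sheath keratin Krt71 had 6763 counts in DST-MNs 1, 22 in DST-MNs 2 and 65 in DST-MNs 3, and 84, 0 and 8 counts in controls 1, 2 and 3.

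**Figure D2:**
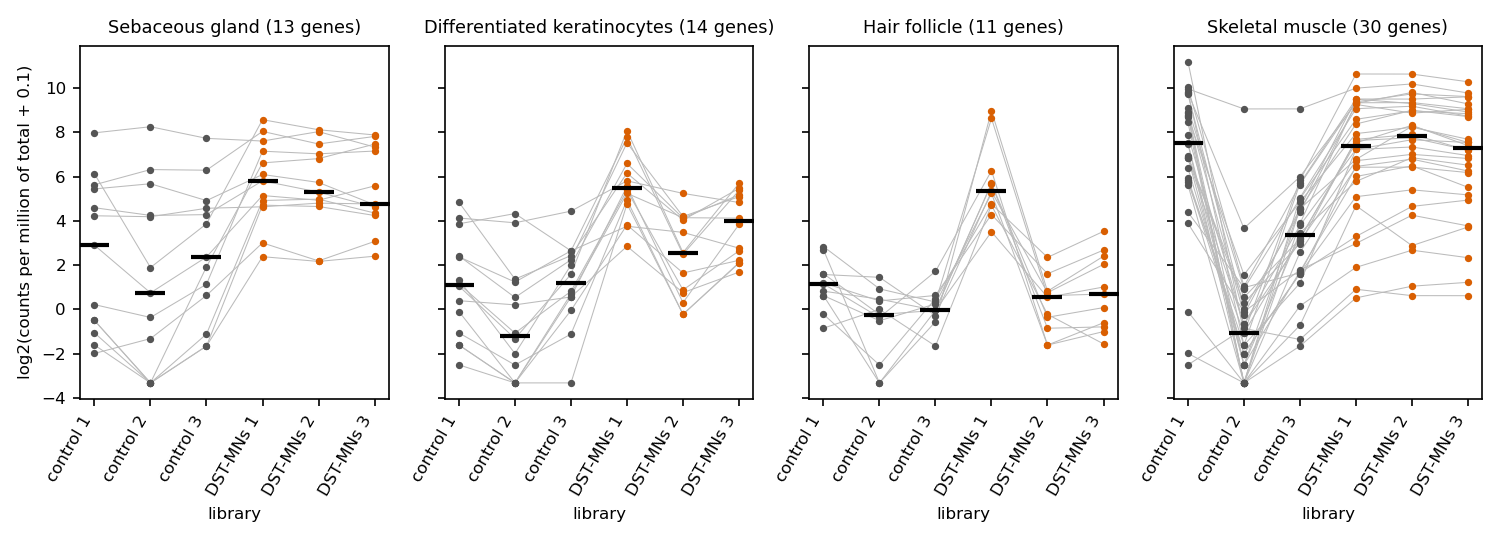
Members of the sebaceous gland, differentiated keratinocyte, hair follicle and skeletal muscle lists are plotted by library (horizontal axis) as log2(CPM + 0.1), with CPM taken from the library total (vertical axis), with grey points for controls, orange points for DST-MNs, thin lines joining each gene and black bars at the list median. The median of the 13 sebaceous genes lay above every control in all 3 treated libraries, that of the 11 hair follicle genes was highest in DST-MNs 1, and that of the 30 muscle genes was lowest in control 2.

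The 10 lower genes of the naming rule included markers of inflammation, matrix turnover and macrophages. Lcn2 (170496), lipocalin 2, an iron-scavenging protein of neutrophils and stressed epithelium, fell from 184 ± 108 to 18.1 ± 3.68 CPM (log2 change -3.35, SE 0.44, adjusted p = 0.0283, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Timp1 (116510), an inhibitor of matrix metalloproteinases, fell from 759 ± 289 to 150 ± 9.71 CPM (log2 change -2.33, SE 0.29, adjusted p = 0.0281). Cd163 (312701), the haemoglobin scavenger receptor of macrophages, fell from 297 ± 38.6 to 88.0 ± 12.6 CPM (log2 change -1.75, SE 0.16, adjusted p = 0.0115). Steap1 (297738), a metalloreductase family member, fell by 1.96 on the log2 scale (SE 0.16, adjusted p = 0.00914). Of these 10 genes, it alone kept its call with each library left out. The peptide hormone genes Adm (25026) and Edn1 (24323), which encode adrenomedullin and endothelin 1, fell by 1.74 and 1.70 on the log2 scale. Plod2 (300901), a collagen lysyl hydroxylase, fell by 1.54, and Rasd1 (64455), Akr1b8 (286921) and Spsb1 (313722) fell by 1.79, 1.17 and 1.12. The counts of Akr1b8 were fractional in all 6 libraries, as for genes that share reads with similar genes, so its level is uncertain. The other 9 kept theirs in 1 to 4 of the 6 cases. Without DST-MNs replicate 3 the adjusted p was 0.147 for Lcn2, 0.136 for Timp1 and 0.0823 for Cd163, their highest with 1 library left out.

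Cytokine and chemokine genes were lower as a list after treatment, with a median log2 change of -1.62 over 21 measured genes (camera adjusted p = 1.36e-07; adjusted p = 0.412 with an estimated correlation). No cytokine gene passed over all genes and 12 were lower adjusted over the list alone. At an unadjusted p below 0.05 there were 13, DESeq2 called 11, Ccl20, Cxcl1, Il11 and Il6 among them, the replicate block 2 and voom 0. The chemokines Ccl20 and Cxcl1 had log2 changes of -2.80 (SE 0.53, adjusted p = 0.0836) and -3.80 (SE 0.81, adjusted p = 0.11, edgeR's quasi-likelihood test, Benjamini-Hochberg), and Il11 one of -2.36 (SE 0.52). Il6 stood at 57.0 ± 70.7 CPM in controls and 2.12 ± 1.37 CPM after treatment (log2 change -4.74, SE 1.10, adjusted p = 0.131). Without control replicate 2 its log2 change was -2.94 (adjusted p = 0.198). Il1b (log2 change -0.85, SE 0.68, adjusted p = 0.573; -0.38 without control replicate 1, -1.28 without control replicate 3, -1.56 without DST-MNs replicate 2 and -0.49 without DST-MNs replicate 3) and Tnf (0.27, SE 0.55, adjusted p = 0.838) had 95% intervals that included 0. Immediate early and heat shock genes, which respond to handling as well as to stimulation, were lower as a list too, at a median of -0.75 over 17 genes (camera adjusted p = 1.29e-05; adjusted p = 0.412 with an estimated correlation). In that list 0 members passed over all genes, 9 had an unadjusted p below 0.05, DESeq2 called 8 and voom 0, and 8 were lower adjusted over the list alone, among them Ier3 (-1.49, SE 0.28), Zfp36 (-1.14, SE 0.21), Junb (-1.10, SE 0.25) and Fos (-1.29, SE 0.30).

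Repair-type (M2) macrophage genes were mostly lower, with negative changes in 11 of 13, though the eosinophil chemokine Ccl24 was higher. Over all genes, Cd163 passed as lower and Ccl24 as higher. Ccl24 (288593) rose from 3.93 ± 0.679 to 20.6 ± 2.42 CPM (log2 change 2.39, SE 0.21, adjusted p = 0.00982, edgeR's quasi-likelihood test, Benjamini-Hochberg). It kept its call in 5 of the 6 cases with 1 library left out, with adjusted p up to 0.0706. The median of this list was -0.83 over 13 genes (camera adjusted p = 8.14e-05; adjusted p = 0.343 with an estimated correlation). There, 2 were higher and 9 lower adjusted over the list alone. Arg1, arginase 1, had a log2 change of -1.47 (SE 0.25, adjusted p = 0.063), Mrc1 one of -0.83 (SE 0.19, adjusted p = 0.131) and Il10 one of -1.44 (SE 0.48, adjusted p = 0.213), or -0.87 without control replicate 2. General monocyte and macrophage genes had a median of -0.12 over 22 genes (camera adjusted p = 0.36). Cd163 was the only member lower over all genes, and 2 were lower adjusted over the list alone. That list passed without control replicate 3 (median -0.23, camera adjusted p = 0.0281) or DST-MNs replicate 2 (-0.28, 0.0487), and its highest median with 1 library left out was 0.06. Inflammatory (M1) macrophage genes had a median of -0.10 over 15 genes (camera adjusted p = 0.897), or -0.64 without control replicate 3 (camera adjusted p = 0.0474), -0.20 without DST-MNs replicate 1 and 0.02 without DST-MNs replicate 3. None passed over all genes, and 1 was higher and 1 lower adjusted over the list alone and with DESeq2, with 4 at an unadjusted p below 0.05. Nos2 had a log2 change of -1.44 (SE 0.78, adjusted p = 0.408), or -2.49 without DST-MNs replicate 2. Neutrophil genes had a median of -0.35 over 13 genes (camera adjusted p = 0.051), or -0.70 with the replicate number as a block, where the list passed (camera adjusted p = 0.0163). Their median was -0.74 without control replicate 3 (camera adjusted p = 0.0015), -1.43 without DST-MNs replicate 2 (0.00305), -0.17 without control replicate 2 and -0.09 without DST-MNs replicate 3 (0.415). Lcn2 fell over all genes, and 1 was higher and 2 lower adjusted over the list alone.

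Antigen presentation genes of MHC class II were higher as a list, with a median log2 change of 0.77 over 14 genes (camera adjusted p = 8.03e-05; adjusted p = 0.412 with an estimated correlation). Over all genes 0 passed, and 7 were higher adjusted over the list alone, 7 with DESeq2 and 8 at an unadjusted p below 0.05. They included the dendritic cell receptor Xcr1 (2.53, SE 0.41, adjusted p = 0.0559, edgeR's quasi-likelihood test, Benjamini-Hochberg), the Langerhans cell lectin Cd207 (3.46, SE 0.70) and the invariant chain Cd74 (1.02, SE 0.22). Interferon response genes had a median of 1.01 over 24 genes (camera adjusted p = 1.83e-05; adjusted p = 0.596 with an estimated correlation). The median was 0.54 without DST-MNs replicate 2 (camera adjusted p = 0.00662), and DST-MNs 3, with a deviation of -0.30, lay below control 1, with one of 0.25. No interferon gene passed over all genes or adjusted over the list alone, DESeq2 called 5, 10 had an unadjusted p below 0.05, and Ifi44 was at 1.25 (SE 0.34). T and NK cell genes had a median of 0.08 and a mean of -0.03 over 19 genes while the test pointed up (camera adjusted p = 0.871). B and plasma cell genes had a median of 0.10 over 7 genes (camera adjusted p = 0.849). Mast cell genes had a median of 0.16 and a mean of 0.13 over 9 genes while the test pointed down (camera adjusted p = 0.871). With 1 library left out the medians ran from -0.24 to 0.25 for T and NK cells, from -0.11 to 0.28 for B and plasma cells and from -0.11 to 0.12 for mast cells. In each of these 3 lists 0 members passed over all genes or adjusted over the list alone, 3, 1 and 2 had an unadjusted p below 0.05, and DESeq2 called 1, 0 and 0.

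Fibroblast genes had a median log2 change of -0.13 over 17 genes (camera adjusted p = 0.00788; adjusted p = 0.412 with an estimated correlation). Its median ran from -0.58 without DST-MNs replicate 3 to 0.00 without DST-MNs replicate 1, where the call was lost (camera adjusted p = 0.0938). No fibroblast gene passed over all genes, DESeq2 called 5, 6 had an unadjusted p below 0.05, and 4 were lower adjusted over the list alone, among them the hyaluronan synthase Has2 (-3.01, SE 0.67) and Pdgfra (-0.77, SE 0.14). Has2 varied among the controls, with 544, 3776 and 1444 counts in controls 1, 2 and 3 against 297, 203 and 255 in DST-MNs 1, 2 and 3. Matrix protein genes had a median of -0.37 over 26 genes (camera adjusted p = 0.00418; adjusted p = 0.596 with an estimated correlation). None of these passed over all genes or adjusted over the list alone, while DESeq2 called 2 and 3 had an unadjusted p below 0.05. The collagen cross-linking enzyme Lox had a log2 change of -1.06 (SE 0.25, adjusted p = 0.131, edgeR's quasi-likelihood test, Benjamini-Hochberg). Col1a1 had one of -0.23 (SE 0.26, adjusted p = 0.691; -0.35 without control replicate 1 and -0.07 without control replicate 3) and Col3a1 one of -0.20 (SE 0.36, adjusted p = 0.821). The matrix list did not pass without control replicate 3 (median -0.08, camera adjusted p = 0.0816) or DST-MNs replicate 1 (0.0738). Proteases and their inhibitors had a median of -0.36 over 19 genes (camera adjusted p = 0.0233; adjusted p = 0.412 with an estimated correlation). In that list Timp1 fell over all genes and 4 were lower adjusted over the list alone, with Adamts1 at -1.42 (SE 0.24). Its call was lost without control replicate 1 (median -0.07, camera adjusted p = 0.226), control replicate 2 (0.054), DST-MNs replicate 1 (0.0938) or DST-MNs replicate 3 (0.064). Myofibroblast, smooth muscle and pericyte genes had a median of -0.05 over 15 genes (camera adjusted p = 0.351), or -0.22 to 0.12 with 1 library left out. No member passed over all genes or adjusted over the list alone, DESeq2 called 1, 1 had an unadjusted p below 0.05, and Acta2 was at -0.38 (SE 0.18, adjusted p = 0.361).

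TGF-β3 was part of the treatment, and the TGF-β list had a median log2 change of -0.19 over 23 genes (camera adjusted p = 0.0378; adjusted p = 0.412 with an estimated correlation). None passed over all genes, and 2 were higher and 4 lower adjusted over the list alone, 1 and 4 with DESeq2 and 3 and 5 at an unadjusted p below 0.05. The lower ones included the target Ccn2 (-1.79, SE 0.35, adjusted p = 0.0886, edgeR's quasi-likelihood test, Benjamini-Hochberg), and the higher ones the binding protein Ltbp4 (0.64, SE 0.12). Tgfb3 itself stood at 53.6 ± 12.3 CPM in controls and 80.2 ± 29.3 after treatment (log2 change 0.58, SE 0.30, adjusted p = 0.381; 0.27 without DST-MNs replicate 3), and Tgfb1 had a log2 change of 0.04 (SE 0.13, adjusted p = 0.904). The list did not pass without DST-MNs replicate 1 (median -0.11, camera adjusted p = 0.0938), without DST-MNs replicate 3 (0.062) or with at least 10 counts required in every library (0.0621). The only comparison was of the whole DST-MNs treatment with untreated wounds, so effects of its single parts cannot be told apart. For spermidine, another part of the treatment, polyamine genes had a median of -0.08 over 21 genes (camera adjusted p = 0.277), or -0.16 to 0.01 with 1 library left out. None passed over all genes and 1, Arg1, was lower adjusted over the list alone, DESeq2 called 1, and 2 had an unadjusted p below 0.05. Odc1, the first enzyme of polyamine synthesis, had a log2 change of -0.20 (SE 0.28, adjusted p = 0.752) and Sat1, which acetylates spermidine, one of -0.02 (SE 0.21, adjusted p = 0.968). Autophagy and mitophagy genes, a process that spermidine is known to induce, had a median of -0.04 over 25 genes (camera adjusted p = 0.573), or -0.12 to -0.03 with 1 library left out. Here 0 passed over all genes, adjusted over the list alone or with DESeq2, and 4 had an unadjusted p below 0.05.

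Endothelial and vessel formation genes were lower as a list, at a median log2 change of -0.49 over 26 genes (camera adjusted p = 1.24e-06; adjusted p = 0.412 with an estimated correlation). No endothelial gene passed over all genes and 6 were lower adjusted over the list alone, 6 with DESeq2 and 11 at an unadjusted p below 0.05. They included von Willebrand factor, Vwf (-0.70, SE 0.12, adjusted p = 0.0723, edgeR's quasi-likelihood test, Benjamini-Hochberg), the endothelial nitric oxide synthase Nos3 (-0.68, SE 0.13) and the VEGF receptor Flt1 (-0.91, SE 0.22). Pecam1 had a log2 change of -0.49 (SE 0.17, adjusted p = 0.233) and Vegfa one of 0.01 (SE 0.50, adjusted p = 0.995). Lymphatic endothelium genes had a median of 0.72 over 7 genes (camera adjusted p = 0.897), or 1.14 without control replicate 1 and 0.34 without control replicate 3, with 0 passing over all genes and 2 higher and 2 lower adjusted over the list alone and at an unadjusted p below 0.05, where DESeq2 called 2 higher and 1 lower.

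Genes of skeletal muscle, nerve and fat, tissues that lie in or under the skin, were higher as lists and varied among the controls. Skeletal muscle genes had a median log2 change of 1.12 over 30 genes (camera adjusted p = 7.84e-08; adjusted p = 0.535 with an estimated correlation). No muscle gene passed over all genes and 1, the myosin light chain Myl2, was higher adjusted over the list alone, while DESeq2 called 2 and 4 had an unadjusted p below 0.05. The muscle list deviated by 2.26, -5.96 and -1.80 in controls 1, 2 and 3 and by 1.70, 2.07 and 1.86 in DST-MNs 1, 2 and 3. Control 1 thus lay above every treated library. The muscle median was 4.65 without control replicate 1, 0.54 without control replicate 2 and 0.67 without control replicate 3, with its camera call kept each time. A kept camera call says little here, since other ways of dividing the libraries 3 against 3 called up to 17 lists. Muscle regeneration genes had a median of 0.45 over 13 genes (camera adjusted p = 0.00874; adjusted p = 0.642 with an estimated correlation), and 0 passed over all genes, adjusted over the list alone, with DESeq2 or at an unadjusted p below 0.05. Their median was 3.72 without control replicate 1, -0.05 without control replicate 3 and -0.10 without control replicate 2, where the call was lost (camera adjusted p = 0.173), and the call was also lost without DST-MNs replicate 2 (0.0811). Nerve and Schwann cell genes had a median of 1.07 over 14 genes (camera adjusted p = 0.00113; adjusted p = 0.412 with an estimated correlation), or 0.64 without DST-MNs replicate 3. Gfra3 (84422), a receptor subunit for artemin, was the 1 member that rose, over all genes and adjusted over the list alone, from 0.646 ± 0.0463 to 3.74 ± 0.879 CPM (log2 change 2.52, SE 0.32, adjusted p = 0.0281, edgeR's quasi-likelihood test, Benjamini-Hochberg). Gfra3 kept its call in 1 of the 6 cases with 1 library left out (adjusted p up to 0.163), and lost it with voom (0.0519), with the replicate block (0.066) and on TPM (0.0554). Adipocyte genes had a median of 0.81 over 16 genes (camera adjusted p = 0.0233; adjusted p = 0.599 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone, and 2 with DESeq2 and at an unadjusted p below 0.05. The adipocyte call was lost without control replicate 2 (median 0.49, camera adjusted p = 0.142), control replicate 3 (0.64, 0.054) or DST-MNs replicate 1 (0.19, 0.214), and the median was 1.51 without control replicate 1.

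Red blood cell genes had a median log2 change of 0.01 over 9 genes (camera adjusted p = 0.539), with a deviation of -2.16 in control 1. Without control replicate 1 the median was -0.46 (camera adjusted p = 0.0483). Bone, cartilage and tooth genes, measured because the spheroids came from dental pulp, had a median of 0.92 over 8 genes (camera adjusted p = 0.0558). That median was 0.63 without control replicate 2 (camera adjusted p = 0.0181), 0.46 without DST-MNs replicate 1 (0.272) and 0.82 without control replicate 1 (0.275). In both lists 0 members passed over all genes or adjusted over the list alone, 0 and 3 had an unadjusted p below 0.05, and DESeq2 called 0 and 1. The labels do not say whether the dental pulp stem cells were rat or human, and only rat genes were counted. The bone, cartilage and tooth list is therefore no measure of those cells.

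Cell cycle genes were lower as a list, at a median log2 change of -0.64 over 28 genes (camera adjusted p = 1.54e-05; adjusted p = 0.599 with an estimated correlation). The median was -1.25 without DST-MNs replicate 1 and -0.41 without DST-MNs replicate 2, and DST-MNs 1, with a deviation of 0.40, lay above control 1, with one of -0.27. No cell cycle gene passed over all genes, adjusted over the list alone or with DESeq2. At an unadjusted p below 0.05 there were 4, 1 higher and 3 lower, and Birc5 was at -1.09 (SE 0.36). Antioxidant response genes had a median of -0.24 over 25 genes (camera adjusted p = 0.00464; adjusted p = 0.412 with an estimated correlation), or -0.38 without DST-MNs replicate 1. None passed over all genes, DESeq2 called 2 higher and 5 lower, 10 had an unadjusted p below 0.05, and 1, the haem oxygenase Hmox1, was lower adjusted over the list alone (log2 change -1.80, SE 0.35). Hypoxia and glycolysis genes had a median of -0.22 over 25 genes (camera adjusted p = 0.00788; adjusted p = 0.453 with an estimated correlation), or -0.37 without DST-MNs replicate 1. Adm was the 1 member lower over all genes and adjusted over the list alone, and Hif1a had a log2 change of -1.08 (SE 0.30). Oxidative phosphorylation genes had a median of -0.02 over 25 genes (camera adjusted p = 0.421), or -0.11 without DST-MNs replicate 1 (camera adjusted p = 0.0369). Senescence and cell death genes had a median of -0.07 over 18 genes (camera adjusted p = 0.229), or -0.18 to -0.06 with 1 library left out. Genes of the AGE receptor and diabetic wound stress had a median of -0.15 and a mean of 0.04 over 16 genes while the test pointed down (camera adjusted p = 0.387). In these 3 lists 0 members passed over all genes or adjusted over the list alone, 1, 4 and 2 had an unadjusted p below 0.05, and DESeq2 called 0, 3 and 1. Of the 37 lists, 21 passed with the preset correlation, 10 higher and 11 lower, and 0 with an estimated correlation, where 3 had an unadjusted p below 0.05. The test fry, which asks whether a list moves on balance one way, called 3. Sebaceous genes were higher (fry adjusted p = 0.013), and repair macrophage (0.013) and TGF-β genes (0.0166) were lower.

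**Figure D3:**
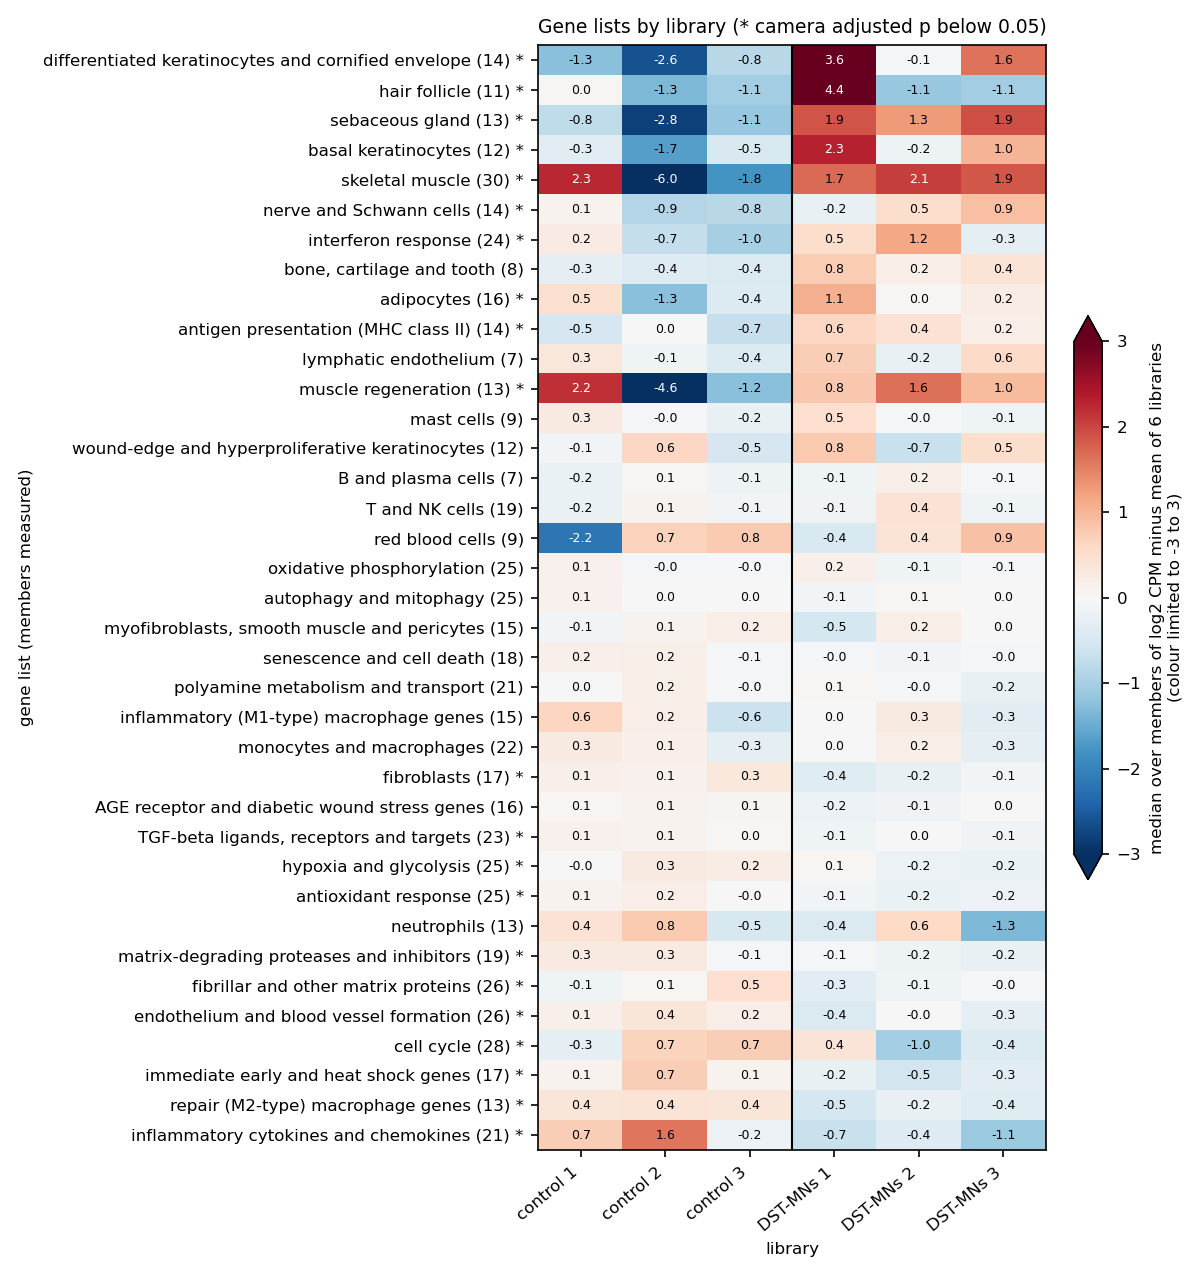
Each cell gives, for a gene list (vertical axis, with its number of measured members) and a library (horizontal axis), the median over members of log2 CPM minus the mean of the 6 libraries, in log2 units, with colour limited to -3 to 3 and a star for camera adjusted p below 0.05. Sebaceous genes lay above every control in all 3 treated libraries, while the muscle list of control 1, at 2.26, lay above every treated library.

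Along the leading principal component of log2 CPM, which held 59.3% of the variance, control 1 lay between the groups, at -1.99 against -91.2 and -51.6 for controls 2 and 3 and 59.6, 37.0 and 48.2 for DST-MNs 1, 2 and 3.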

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

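The test on deposited TPM was chosen after seeing the data; the others were planned. Against 112 changed genes, 95 higher, 17 lower and 107 at least 2-fold, the counts with at least 10 counts in every library were 38, 28, 10 and 37, where 52 of the 112 genes stayed in the test and 38 were still called. With DESeq2 they were 1070, 678, 392 and 694, and all of the 112 were among them. The TPM test gave 8 lower genes and glmTreat against a 1.5-fold change 70. Leaving out 1 library gave 14 (without DST-MNs replicate 3) to 402 (without control replicate 1) changed genes, 13 to 314 higher, 1 to 88 lower and 14 to 359 at least 2-fold, and all 112 kept their direction. Lists past the threshold numbered 0 with an estimated correlation and 3 with fry, against 21. Apart from the stricter filter, which tested fewer genes, the cause was not tested. Size factors, upper-quartile factors, total counts, no filter and voom gave 106, 124, 134, 106 and 95 changed genes. Total counts moved the median of all genes by 0.12 and the percentage of higher calls from 84.8 to 91.0, and gave positive medians to 5 lists that were not called: autophagy (0.09), myofibroblasts (0.05), oxidative phosphorylation (0.10, and 0.0011 with upper-quartile factors), polyamines (0.04) and senescence (0.04). With the replicate number as a block, 123 genes changed, 57 of the 112 among them. Same-number correlations were -0.0245, 0.101 and 0.109, and controls 1, 2 and 3 correlated best with DST-MNs 2, 2 and 3, so not every library correlated best with its own number. The 25 named genes past the threshold kept their sign in all 361 alternative values, 267 still past it and 94 not. Genes past no threshold changed sign in 18 of 1399 values and passed in 80. Sat1 was at 0.0918 with total counts, 0.0094 with voom, 0.0103 with the block and 0.15 with TPM. Vegfa was at -0.0045 with no filter, -0.0043 with DESeq2, -0.0144 with voom and -0.0557 with the block. Leave-one-out ranges were -0.60 to 0.47 for Vegfa, -0.21 to 0.18 for Sat1, -0.0482 to 0.12 for Tgfb1, -0.45 to 0.12 for Col3a1, -0.16 to 4.55 for Krt86, -0.20 to 0.80 for Tnf and -0.60 to 0.0055 for Odc1, and list medians ran from -0.46 to 0.42 for red blood cells and from -0.16 to 4.71 for the hair follicle. At this depth and spread, 2-fold changes were mostly missed on simulated counts.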

Other observations

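The 5 added lists, the genes named from them and the tests of patterns below were chosen after the results had been seen, except the splits of the libraries, which were planned, and the glucocorticoid test, whose list was prompted by called genes but whose bound was set before its members' values were seen. Of the 5 lists, the other 4 kept genes that had already been seen to move, so the set tests run on them partly restate those genes and are not given, and these lists are described by their medians and by the members that passed over all genes.

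Cholesterol synthesis genes had a median log2 change of 0.82 over 20 genes, of which 3 rose over all genes (among them Hsd17b7, 1.10). Epidermal barrier lipid genes had a median of 0.74 over 13 genes, and 4 rose, Elovl4, the ceramidase Acer1 (5.66), the ceramide synthase Cers3 (6.10) and Elovl1 (0.65). Peroxisomal fatty acid oxidation genes had a median of 0.36 over 13 genes, and Hacl1 (3.03), Pxmp4 (2.12) and Crot (1.08) rose. Hyaluronan matrix genes had a median of -0.64 over 11 genes, with 0 passing over all genes, 5 lower with DESeq2 and 6 lower at an unadjusted p below 0.05. The genes were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment.

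The 6 libraries can be split 3 against 3 in 10 ways, too few for a share below 0.05. The real split, 1 of 10 with counts as large in each case, gave 112 changed genes, 95 and 17 by direction, 107 at least 2-fold and 21 lists, and the highest of the other splits gave 1, 1, 0, 1 and 17.

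Sebaceous and epidermal genes were higher in treated wounds as lists, where 4 of 13 sebaceous and 0 of 14 differentiated and 0 of 12 basal keratinocyte genes passed edgeR's quasi-likelihood test over all genes and 9, 10 and 2 that of DESeq2 (adjusted p = 0.343, 0.412 and 0.448 with an estimated correlation). Scaling did not account for it, since under each other scaling the medians of the 3 lists were 2.20 or higher and at least 89 of the 95 higher genes kept their call, but more intact skin in the treated pieces stays open, since the test of it (treated libraries with all 7 skin, fat, muscle and nerve lists above every control, 0) could not decide: control 1 lay above all 3 treated libraries for muscle, above DST-MNs 2 and 3 for hair follicle and fat and above DST-MNs 1 for nerve, while controls 2 and 3 lay below every treated library in the 7 lists, except that the hair list of DST-MNs 2 (-1.13) lay below that of control 3 (-1.05). Whether regrown epidermis alone was the cause could not be decided. The sebaceous list lay above every control in all 3 treated libraries, which restates the pattern, and so did both epidermal lists. The test tried first, for treated libraries with sebaceous but neither epidermal list above every control, found 0 and by itself decided nothing. A test of another explanation, chosen after that first outcome, found that differentiated keratinocyte genes varied more than sebaceous genes over the treated libraries (median SD 1.44 against 0.319, difference 1.12, permutation p = 0.00198, two-sided, over genes, which are not independent). This argues against a sebaceous signal carried in a fixed ratio by the differentiated epidermis in each piece, but only as far as the lists stand for those tissues. Elovl4 of the sebaceous list is also counted above among epidermal barrier lipid genes. The keratinocyte list holds genes with few counts in some libraries, such as Flg with 364, 10 and 52 in DST-MNs 1, 2 and 3. Basal keratinocyte genes were not compared. Sebaceous members with a clear signal in controls, such as Fasn at 72.1 CPM, may vary less for that reason. Which part of the wound and its edge each piece held may differ between the groups, and this cannot be separated from the treatment here, so appendage regrowth under treatment stays an untested hypothesis.

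Cytokine and immediate early genes were lower in treated wounds as lists, where 0 of 21 and 0 of 17 passed edgeR's quasi-likelihood test over all genes and 11 and 8 that of DESeq2 (adjusted p = 0.412 with an estimated correlation for both). The medians go against an even dilution of all wound-bed genes by other tissue. The cytokine median lay 1.38 below that of fibroblast, macrophage and matrix genes (difference -1.38, permutation p = 1e-05, two-sided, the smallest the permutations give). The immediate early median lay 0.51 below (difference -0.51, permutation p = 0.00291, two-sided), both over genes, which are not independent. Both lists were picked after their low medians were seen, and the permutations shuffle genes, not animals. Dilution is therefore not excluded. Control replicate 2 alone did not set the direction of the cytokine list, since without it the median was -1.23 (camera adjusted p = 3.65e-07, within 3.06e-14 to 0.000163 over the libraries left out). That the camera call was kept says little, since other splits of the libraries called up to 17 lists. Median deviations of the cytokine list were 0.74, 1.61 and -0.18 in controls 1, 2 and 3 and -0.67, -0.38 and -1.11 in DST-MNs 1, 2 and 3. Time from collection to freezing, which may change immediate early genes, and a lower inflammatory state after treatment both stay open, and neither was tested.

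Fkbp5 (-0.84), Rasd1 and Cd163, which respond to glucocorticoids, were all lower in treated wounds. A lower glucocorticoid response is a candidate explanation, since 14 other targets had a median of -0.52, with 7 lower adjusted over the list alone. The camera adjusted p was 0.000555, and with an estimated correlation the unadjusted p was 0.0494 and the adjusted p over the 5 lists 0.0823. The bound asked for a negative median and a p below 0.05 with an estimated correlation, and was met only unadjusted. The evidence is narrow: Tsc22d3 (-0.10), Per1 (-0.38), Klf15 (0.01), Pdk4 (-0.13), Zbtb16 (0.43), Ddit4 (0.04) and Mertk (0.35), the other 7 members, did not pass even over the list alone. Fewer macrophages in general did not account for Cd163, since 21 other general macrophage markers had a median of -0.12 and the lowest was at -0.83, against -1.75 for Cd163. Fewer repair-type macrophages stay open and were not tested. Their list, which holds Cd163, had a median of -0.83, with 9 lower and 2 higher adjusted over the list alone. In it Arg1 was at -1.47 and Il10 at -1.44, while Ccl24 was at 2.39. The cytokine list was lower too (median -1.62), and how this bears on a lower glucocorticoid response was not tested. Hormone levels were not analysed here, and the glucocorticoid hypothesis was found and tested on the same data.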
